A study of Mus musculus with 36 samples.

How the data were processed

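RNA sequencing values of 36 mouse libraries were analysed: 9 UPPL and 11 BBN primary bladder tumours, 4 UPPL1541, 2 BBN963 and 4 MB49 line-derived tumours, and 6 cultures (UPPL1541, BBN963, MB49 and 3 KT lines). Per the labels, UPPL mice carry Upk3a-CreERT2 with floxed Trp53, and BBN mice were given N-butyl-N-(4-hydroxybutyl)nitrosamine. The genotype label of the UPPL1541 culture reads Ctrl and was not used to group. The meaning of KT is not given, and the 3 KT lines were summarized together by name only. RNA was isolated with RNeasy and libraries were made with the TruSeq Stranded mRNA kit, per the labels' protocols. RSEM, Picard 1.64, SAMtools and the mm9 genome are named in the submitters' processing notes, without the role of each.

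The deposited file holds signal values for 21705 genes, which are RSEM gene estimates scaled per library so that the 75th percentile of values above 0 is 1000 (998.9 to 1000 across columns). Dividing by each library's smallest step gave whole numbers for 92.0 to 96.3 percent of values above 0 (within 0.02 of a whole number), read here as reads, with 9.29 to 17.9 M reads per library. In 9 columns the lowest values were fractions of a read. The most frequent low value was 1 read in every culture and 2 to 19 reads in tumours, so a value of 0 in a tumour may mean fewer than that many reads. Differences in genes with few reads are therefore less precise in tumours than the read totals imply.

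Values were taken as log2(value + 1) and fitted with limma 3.58.1 (trend) in R 4.3.3, on genes at or above 1 percent of the median 75th percentile in at least as many libraries as the smallest group compared (3 for cultures). Primary tumours were fitted alone; the 3 groups of line-derived tumours shared 1 fit, as did the 4 groups of UPPL and BBN tumours and the 6 groups of tumours and cultures. A gene passed at a Benjamini-Hochberg adjusted p of 0.05. The 8 comparisons, the gene lists (32 fixed, 30 tested, 502 of 509 genes found), the scores and the rule for naming genes were chosen before the data were examined. Lists were tested with camera at a correlation of 0.01, then with an estimated correlation. Scores are the mean log2 value over a list, compared by exact permutation tests with adjustment over the 8 scores. The comparison of line-derived tumours with cultures includes line as a factor. The p-values measure spread between samples; tumours of 1 line are not independent lines or mice of different origin.

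Genes were named by rule: those of the genotype; the 6 largest rises and falls among primary tumours and the 3 largest elsewhere, with an adjusted p under the threshold and a mean of at least 100 in the higher group, skipping predicted, Riken and receptor segment symbols; and for each list described, its first 2 genes and up to 2 further with the smallest adjusted p. In the cultures the first 2 genes of each list described were eligible. Alternatives were a pseudocount of 10, no filter and a stricter filter, quantile normalization, median-of-ratios scaling, array weights, no variance trend, a fit over all 36 libraries, a block on the tumour number, leaving out the primary tumours whose numbers the lines carry, and leaving out each library. An edgeR 4.0.16 quasi-likelihood fit on recovered reads, and leaving out the 5 libraries whose most frequent low value was 10 reads or more, were added after seeing the data. The scripts were tested on simulated data: in the primary comparison 39 percent of 2-fold and 79 percent of 4-fold changes were recovered. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. No coordinates were used. Some genes that the naming rule picks are not reported here.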

Results

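Trp53, which encodes the p53 tumour suppressor and is floxed in the UPPL mice per the labels, was lower in the 9 UPPL primary tumours (74.98 ± 44.4 deposited units, mean ± SD) than in the 11 BBN primary tumours (1518 ± 550.0; log2 fold change -4.41, SE 0.289, adjusted p = 3.0e-09). All 9 UPPL tumours lay below every BBN tumour in Trp53 (exact permutation test, adjusted p = 3.6e-05 over 3 genes). Upk3a, a uroplakin gene whose promoter drives the recombinase, did not pass (2090.3 ± 2920.1 against 147 ± 246; log2 fold change 3.42, SE 1.88, adjusted p = 0.20). Upk3a was listed at 0 in UPPL1591 and UPPL1595 and at 8508 in tumour UPPL1612. The line-derived tumours kept the Trp53 difference: 93.3 ± 31.6 in 4 UPPL tumours, 525 ± 176 in 2 BBN tumours and 1353 ± 158 in 4 MB49 tumours (-2.49, SE 0.307, adjusted p = 2.8e-04 against BBN, and -3.89, SE 0.251, adjusted p = 3.3e-07 against MB49). These values sum all exons of a gene, so a deletion of some exons need not bring a gene to 0.

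**Figure D1:**
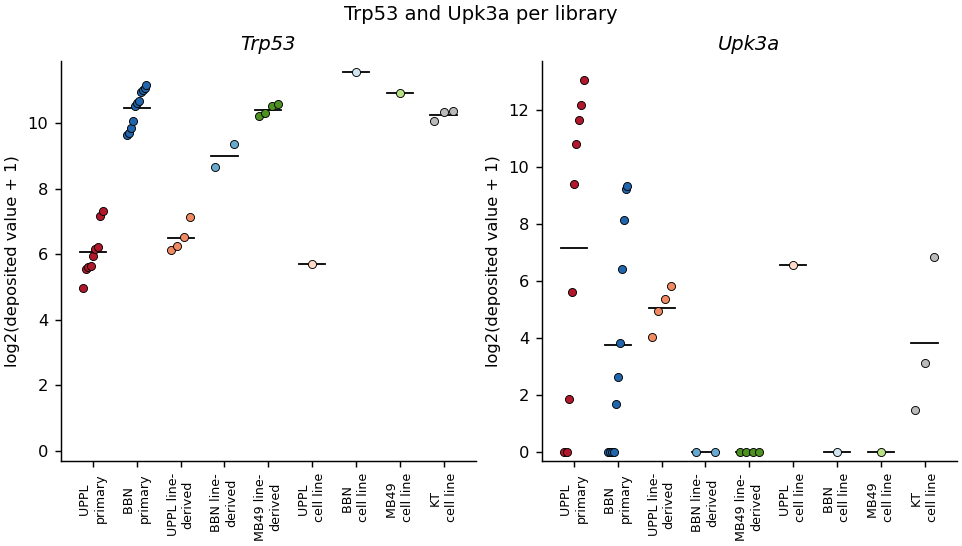
Trp53 and Upk3a in the 36 libraries as log2(deposited value + 1), by group; each dot is 1 library and each line the group mean. Trp53 lay lower in every UPPL primary tumour than in any of the 11 BBN primary tumours.

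Among uroplakin genes, which encode the plaques of the superficial urothelial cell, Upk1a (7065 ± 5434 in UPPL against 230.0 ± 342 in BBN; log2 fold change 6.44, SE 1.14, adjusted p = 8.3e-04), Upk3b (5.98, SE 0.990) and Upk2 (3.70, SE 1.05) were higher in UPPL primary tumours and Upk3a did not pass. Krt20, a keratin of the same cells, did not pass either (0.37; adjusted p = 0.78). Fabp4, which encodes a fatty acid binding protein, was higher by a log2 fold change of 5.97, SE 0.991, and Pparg, which encodes the nuclear receptor that drives it, by 2.92, SE 0.560. In the list of luminal urothelial markers, 11 of 29 were higher, 0 were lower and 18 did not pass (camera adjusted p = 9.4e-08). Luminal genes called numbered 13 and 0 adjusted over the list alone, and the list gave adjusted p = 0.15 with an estimated correlation. In the list of PPAR target genes, which shares Pparg and Fabp4 with the luminal list, 5 of 15 were higher, 1 was lower and 9 did not pass (camera adjusted p = 2.8e-05). PPAR genes called numbered 6 and 1 adjusted over the list alone, and the list gave adjusted p = 0.15 with an estimated correlation. Acsl3, an acyl-CoA synthetase gene, was among the higher members (1.33, SE 0.211), and Angptl4 did not pass (0.21). The luminal score per tumour was 10.91 ± 0.667 in UPPL and 9.16 ± 1.01 in BBN, and 5 of the 9 UPPL tumours lay above every BBN tumour (exact permutation test, adjusted p = 0.0013 over the 8 scores).

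Krt5 (139116 ± 87881 against 142989.8 ± 36119) and Krt14 (86846 ± 69321 against 121334 ± 62767), the keratins of the basal urothelial layer, were abundant in UPPL and BBN primary tumours and did not pass. Krt17, a keratin of stressed and basal cells, was lower in UPPL tumours (2276 ± 3344 against 16596 ± 7072; log2 fold change -4.80, SE 0.964, adjusted p = 0.0021), as was Cdh3, which encodes P-cadherin (-0.998, SE 0.219). Of the basal list, 1 of 24 was higher, 3 were lower and 20 did not pass (camera adjusted p = 0.74). Basal genes called numbered 1 and 3 adjusted over the list alone. The basal score did not pass (difference -0.46, exact permutation adjusted p = 0.34), while luminal minus basal was higher in UPPL by 2.21 (exact permutation adjusted p = 0.0013). Among squamous differentiation genes, Ivl, an envelope protein gene, was higher in UPPL (1.77, SE 0.393), Sprr1a too (2.03, SE 0.704), and Sprr1b did not pass. The squamous list test was not passed and leaned to higher values, opposite to the list median of -0.79 (camera adjusted p = 0.61). Cldn4, a tight junction gene, was higher (1.75, SE 0.342), with Prss8 (0.99, SE 0.291) and Ocln (1.25, SE 0.424), while Cdh1 did not pass (0.27). Of the epithelial junction list, 3 of 17 were higher, 0 were lower and 14 did not pass (camera adjusted p = 0.016). Junction genes called numbered 3 and 0 adjusted over the list alone, and the list gave adjusted p = 0.42 with an estimated correlation, and camera gave 0.13 under quantile normalization.

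**Figure D2:**
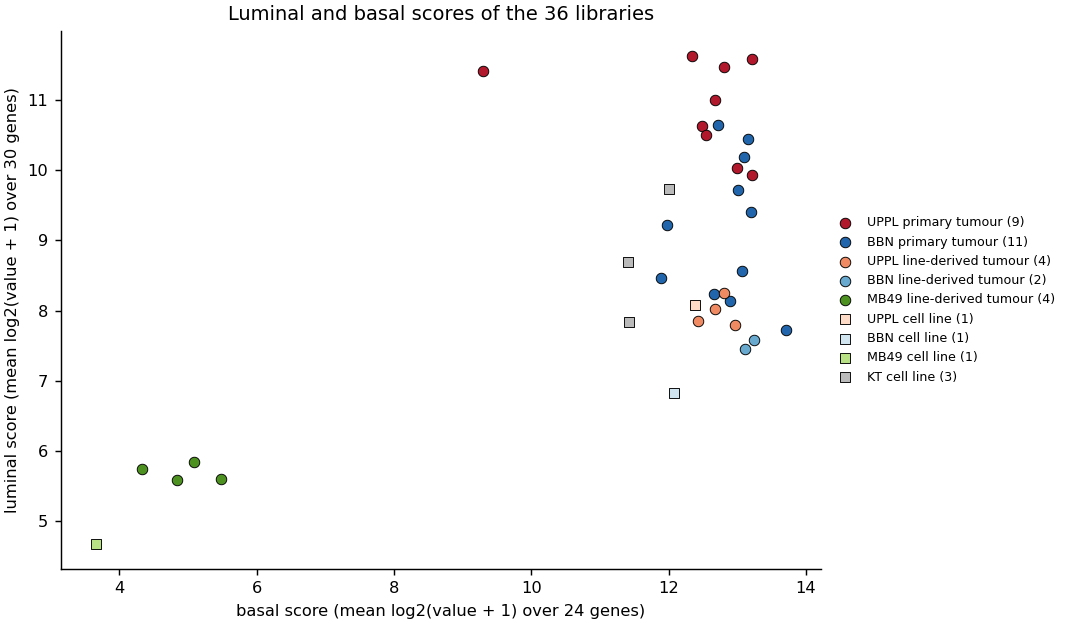
Luminal score against basal score of the 36 libraries, each score the mean log2(value + 1) over the genes of the list; circles are tumours, squares cultures. Primary tumour UPPL1694 (basal score 9.30) and the MB49 libraries lie apart from the others.

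Antigen presentation and interferon genes were lower in UPPL than in BBN primary tumours. Gbp2, an interferon-induced GTPase gene, stood at 174 ± 186 against 1587 ± 1313 (log2 fold change -3.61, SE 0.636, adjusted p = 8.1e-04), with Irf1 (-1.25, SE 0.190) and the T cell attractant gene Cxcl9 (-4.34, SE 0.912) lower as well. Of the interferon response list, 0 of 23 were higher, 13 were lower and 10 did not pass (camera adjusted p = 1.8e-06). Interferon genes called numbered 0 and 19 adjusted over the list alone, and the list gave adjusted p = 0.41 with an estimated correlation. Cd74 and H2-Aa, which serve peptide loading on MHC class II, were lower (-1.82, SE 0.422 and -1.81, SE 0.432), as were Ctss (-1.9999, SE 0.341) and H2-Ab1 (-2.13, SE 0.461). Of the MHC class II list, 0 of 8 were higher, 7 were lower and 1 did not pass (camera adjusted p = 1.2e-04). MHC class II genes called numbered 0 and 7 adjusted over the list alone, and the list gave adjusted p = 0.41 with an estimated correlation. B2m, the light chain of MHC class I, was lower (4044 ± 3559 against 14022 ± 8729; -1.86, SE 0.471), with Nlrc5, the activator of the class I genes (-3.83, SE 0.930), and Psme1 (-0.76, SE 0.189), while Tap1 did not pass. Of the MHC class I list, 0 of 17 were higher, 4 were lower and 13 did not pass (camera adjusted p = 0.0057). MHC class I genes called numbered 0 and 10 adjusted over the list alone, and the list gave adjusted p = 0.64 with an estimated correlation.

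Macrophage genes were lower in UPPL primary tumours. Csf1r, the receptor that maintains macrophages, stood at 85.7 ± 84.7 against 372 ± 279.9 in BBN (log2 fold change -2.15, SE 0.512, adjusted p = 0.0065); the complement genes C1qc (-1.76, SE 0.334) and C1qb (-1.73, SE 0.332) were lower too, and Cd68 did not pass. Of the macrophage and monocyte list, 0 of 19 were higher, 10 were lower and 9 did not pass (camera adjusted p = 5.5e-05). Macrophage genes called numbered 0 and 11 adjusted over the list alone, and the list gave adjusted p = 0.41 with an estimated correlation. The macrophage score per tumour was 5.85 ± 0.847 in UPPL and 7.35 ± 0.734 in BBN, with 5 of 9 UPPL tumours below every BBN tumour (exact permutation adjusted p = 0.0013). Lymphocyte genes stood near the detection limit: Cd4, the helper T cell receptor gene (6.599 ± 8.84 against 33.9 ± 32.3; -2.52, SE 0.720), and Lck (-2.17, SE 0.755) were lower, and Cd3e and Cd3g were left out by the filter on low values. Neither kept its call under quantile normalization (adjusted p 0.068 to 0.13), nor did Lck under median-of-ratios scaling (0.057). Of 5 tested T cell genes 2 were lower and 3 with adjustment over the list alone (camera adjusted p = 0.49), but the scores over all detected members were lower for T cells (1.74 ± 0.324 against 2.57 ± 0.943, exact permutation adjusted p = 0.021, and 0.12 under quantile normalization) and cytotoxic lymphocytes (0.54 ± 0.339 against 1.39 ± 0.653, exact permutation adjusted p = 0.0013). Foxp3, the regulator of regulatory T cells, was lower (1.72 ± 3.81 against 18.3 ± 11.9; -2.97, SE 0.817), and Il2ra did not pass. Pecam1 and Cdh5, endothelial junction genes, did not pass, and Esam was higher in UPPL (1.499, SE 0.324; endothelial list camera adjusted p = 0.74).

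**Figure D3:**
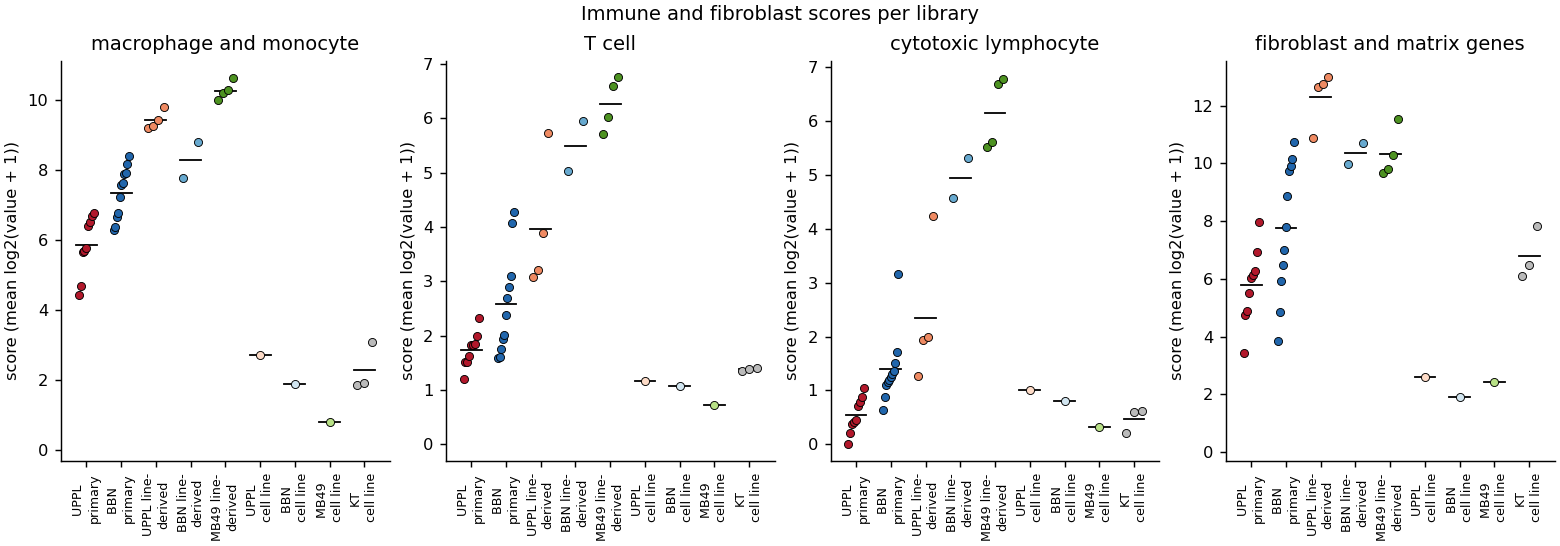
Macrophage, T cell, cytotoxic lymphocyte and fibroblast scores of the 36 libraries by group (mean log2(value + 1) over the list); each dot is 1 library and each line the group mean. The 6 cultures stand lowest in the macrophage panel, and the 10 line-derived tumours stand above most primary tumours.

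Some matrix and mesenchymal genes were lower in UPPL primary tumours, with a wide spread, while most members of the lists did not pass. Col1a1, a fibrillar collagen gene (417 ± 254 against 3493 ± 4099; log2 fold change -2.45, SE 0.857, adjusted p = 0.0496), and Col5a1 (-2.37, SE 0.829) were lower, and Pdgfra did not pass. Both collagen calls were lost under quantile normalization (adjusted p 0.063 to 0.073) and median-of-ratios scaling (0.059 to 0.060). Of the fibroblast and matrix list, 0 of 18 were higher, 2 were lower and 16 did not pass (camera adjusted p = 0.0071). Fibroblast genes called numbered 0 and 9 adjusted over the list alone, and the list gave adjusted p = 0.79 with an estimated correlation. The fibroblast score differed by -1.99 (exact permutation adjusted p = 0.048, and 0.061 under quantile normalization). Cdh11 (-3.29, SE 0.941) and Twist2 (-3.29, SE 0.965), genes of mesenchymal cells, were lower, while Vim and Zeb1 did not pass. Of the mesenchymal list, 0 of 15 were higher, 4 were lower and 11 did not pass (camera adjusted p = 0.036). Mesenchymal genes called numbered 0 and 6 adjusted over the list alone, and the list gave adjusted p = 0.64 with an estimated correlation. Des, a muscle filament gene, was lower (-4.45, SE 1.49), with Kcnmb1 (-3.17, SE 0.998) and Actg2 (-3.97, SE 1.37), and Myh11 did not pass (smooth muscle list camera adjusted p = 0.15, and camera gave 0.045 under quantile normalization). Twist2, Des and Actg2 lost their calls under quantile normalization (adjusted p 0.053 to 0.089), and Actg2 under median-of-ratios scaling (0.052).

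Some genes of oxidative defence and of hypoxia were higher in UPPL primary tumours, while most members of the lists did not pass. Gstm1, a glutathione transferase gene (19924 ± 11788 against 3635 ± 2933; log2 fold change 3.06, SE 0.655, adjusted p = 0.0033), and Hmox1, which encodes haem oxygenase (2.17, SE 0.364), were higher, and Nqo1 and Gclc did not pass. Of the NRF2 and xenobiotic list, 5 of 20 were higher, 0 were lower and 15 did not pass (camera adjusted p = 1.8e-06). NRF2 genes called numbered 5 and 0 adjusted over the list alone, and the list gave adjusted p = 0.15 with an estimated correlation. Hk2, the hexokinase gene of glycolysis (1.498, SE 0.270), Ndrg1 (2.29, SE 0.468) and Vegfa, the vessel growth factor gene (1.15, SE 0.384), were higher, and Slc2a1 did not pass. Vegfa lost its call under quantile normalization (adjusted p = 0.051). Of the hypoxia list, 6 of 18 were higher, 0 were lower and 12 did not pass (camera adjusted p = 2.9e-06). Hypoxia genes called numbered 8 and 0 adjusted over the list alone, and the list gave adjusted p = 0.41 with an estimated correlation. The p53 and FOXO target lists did not pass. Among p53 targets, Pmaip1, a death gene, was higher in UPPL (1.45, SE 0.363), Ercc5, a repair gene, was lower (-0.62, SE 0.189; not passed under quantile normalization, adjusted p = 0.088, or median-of-ratios scaling, 0.060), and Cdkn1a (0.59) and Mdm2 (-0.45) did not pass; the list test leaned to higher values, opposite to its median of -0.18 (camera adjusted p = 0.72). Among FOXO targets, which serve stress resistance and metabolism, Klhl24 was higher (1.17, SE 0.333), Irs2 and Pik3ip1 did not pass, and the list median of -0.27 lay opposite to the side the test leaned to (camera adjusted p = 0.74). Mki67 and Top2a, genes of dividing cells, did not pass, and Cdc20 was lower (-1.02, SE 0.244; proliferation list camera adjusted p = 0.72).

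**Figure D4:**
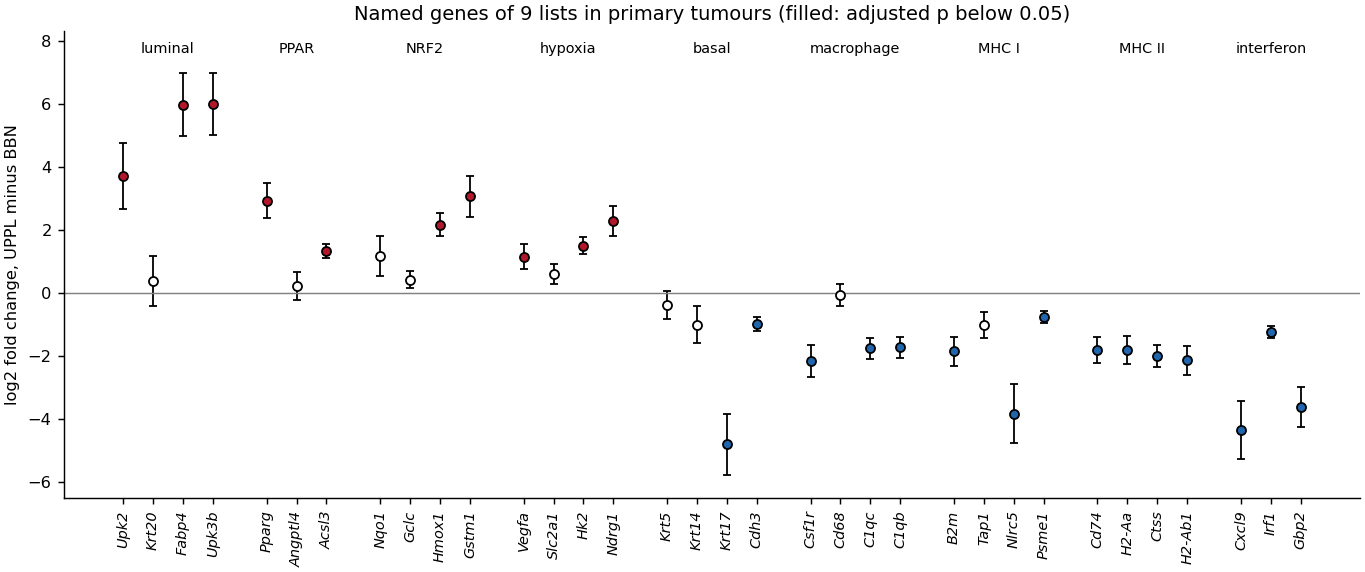
Log2 fold change of named genes, UPPL minus BBN primary tumours (9 and 11 libraries), by list; bars are 1 SE, filled points passed and open points did not. Filled luminal, NRF2 and hypoxia genes lay above 0, filled macrophage, MHC and interferon genes below.

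Across the primary tumours, 2371 of 12818 genes passed, 732 higher and 1639 lower in UPPL (30.9 percent higher). That split depends on scaling: 938 and 987 under quantile normalization, 1086 and 1147 under median-of-ratios scaling and 1098 and 893 with edgeR on recovered reads. The median of all genes moved from -0.19 as deposited to -0.039 under quantile normalization, so small differences are relative to that shift. Besides Upk1a, Upk3b and Fabp4, the genes with the largest rise were Ugt2b34, a glucuronosyl transferase gene (8019 ± 5319.6 against 479.6 ± 681; 6.67, SE 1.29), Smc1b, a meiotic cohesin gene (6.23, SE 0.655), and Ctnnd2, a catenin gene (5.48, SE 0.890). Among the largest falls were Lgals7, a galectin gene of stratified epithelium (524 ± 766 against 10826 ± 8232; -6.48, SE 1.30), Hoxb9 (-6.45, SE 0.893), the Wnt antagonist gene Sfrp1 (-5.73, SE 1.003), Pax9 (-5.42, SE 0.763) and the activin antagonist gene Fst (-5.37, SE 1.09). No list call in the primary comparison held with an estimated correlation between genes. Of all the comparisons, the list calls that held with it were luminal and NRF2 genes, lower in UPPL line-derived than primary tumours, squamous, basal and junction genes, higher in BBN than MB49 tumours, and cytotoxic genes, higher in BBN line-derived than primary tumours.

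Epithelial genes set the 4 UPPL line-derived tumours apart from the 4 MB49 tumours. Krt5 stood at 127075 ± 7513 against 6.36 ± 4.398 (log2 fold change 14.34, SE 0.417, adjusted p = 6.3e-10), Krt14 at 141693 ± 30088 against 412 ± 203, and Cdh1, the epithelial cadherin gene, at 10997 ± 983 against 32.0 ± 21.4 (8.59, SE 0.347). Krt1 (141057 ± 43826 in UPPL), Krt13 (41741 ± 11751), Dsc3, Ivl, Psca, Grhl3, Cldn4, Esrp1 and Rab25 were listed at 0 in all 4 MB49 tumours and passed (adjusted p = 4.8e-12 for Krt1 and 5.9e-11 for Cldn4). Dsp, a desmosome gene, rose by 14.85, SE 0.287 on the log2 scale, and Krt20 by 11.49, SE 0.504. Of the squamous list, 19 of 19 rose, 0 fell and 0 did not pass (camera adjusted p = 9.2e-17). Squamous calls were 19 and 0 adjusted over the list alone, and the list gave adjusted p = 0.053 with an estimated correlation. Of the basal list, 21 of 24 rose, 2 fell and 1 did not pass (camera adjusted p = 1.4e-11). Basal calls were 21 and 2 adjusted over the list alone, and the list gave adjusted p = 0.078 with an estimated correlation. Of the junction list, 16 of 17 rose, 1 fell and 0 did not pass (camera adjusted p = 1.2e-09). Junction calls were 16 and 1 adjusted over the list alone, and the list gave adjusted p = 0.053 with an estimated correlation. Of the luminal list, 17 of 25 rose, 5 fell and 3 did not pass (camera adjusted p = 0.0022). Luminal calls were 18 and 5 adjusted over the list alone, and the list gave adjusted p = 0.24 with an estimated correlation. The basal score was 12.72 ± 0.226 against 4.93 ± 0.484 and every UPPL tumour lay above every MB49 tumour (exact permutation adjusted p = 0.038, unadjusted p = 0.029, the smallest that 4 against 4 allows).

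Immune genes ran the other way, lower in UPPL than in MB49 tumours. Gzmb and Prf1, which arm cytotoxic lymphocytes, stood at 19.9 ± 31.5 against 519 ± 323 (log2 fold change -5.60, SE 0.844, adjusted p = 2.3e-04) and 5.53 ± 7.61 against 216 ± 105 (-5.91, SE 0.922), with Cd8a (-5.51, SE 1.27) and Ifng (-4.92, SE 0.866) also lower. Of the cytotoxic list, 0 of 16 rose, 14 fell and 2 did not pass (camera adjusted p = 8.8e-05). Cytotoxic calls were 0 and 14 adjusted over the list alone, and the list gave adjusted p = 0.49 with an estimated correlation. Cd3g, a T cell receptor complex gene, fell by 4.21, SE 1.12 on the log2 scale, and Cd3e, Cd3d and Cd28 fell too; of the T cell list, 0 of 17 rose, 10 fell and 7 did not pass (camera adjusted p = 0.0085). T cell calls were 1 and 12 adjusted over the list alone, and the list gave adjusted p = 0.49 with an estimated correlation. B2m (-2.63, SE 0.577), Tap1 (-2.95, SE 0.477) and Cd74 (-2.28, SE 0.414) were lower, as was Cxcl9 (-4.27, SE 1.18). Of the MHC class I list, 0 of 17 rose, 15 fell and 2 did not pass (camera adjusted p = 1.0e-06). MHC class I calls were 0 and 15 adjusted over the list alone, and the list gave adjusted p = 0.49 with an estimated correlation. Of the class II list, 0 of 11 rose, 10 fell and 1 did not pass (camera adjusted p = 8.8e-05). MHC class II calls were 0 and 10 adjusted over the list alone, and the list gave adjusted p = 0.49 with an estimated correlation. Of the interferon list, 0 of 24 rose, 23 fell and 1 did not pass (camera adjusted p = 1.6e-07). Interferon calls were 0 and 23 adjusted over the list alone, and the list gave adjusted p = 0.49 with an estimated correlation. Cd274, which encodes PD-L1 (-1.84, SE 0.345), Pdcd1 (-3.58, SE 0.977) and Ido1, which depletes tryptophan (-7.98, SE 1.16), were lower. Of the checkpoint list, 0 of 15 rose, 10 fell and 5 did not pass (camera adjusted p = 0.0058). Checkpoint calls were 0 and 10 adjusted over the list alone, and the list gave adjusted p = 0.38 with an estimated correlation. Msr1, a scavenger receptor gene of macrophages, was lower (-2.85, SE 0.192) and Arg1, the arginase gene, higher (5.77, SE 0.447). Of the macrophage list, 2 of 20 rose, 12 fell and 6 did not pass (camera adjusted p = 0.0046). Macrophage calls were 2 and 13 adjusted over the list alone, and the list gave adjusted p = 0.49 with an estimated correlation. The cytotoxic score was 2.35 ± 1.29 against 6.14 ± 0.673, lower in 4 of 4 UPPL tumours (exact permutation adjusted p = 0.038), and the T cell score did not pass (exact permutation adjusted p = 0.057).

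Among the other lists of the UPPL and MB49 tumours, Mki67 (-1.32, SE 0.148) and Top2a (-1.26, SE 0.123) were lower in UPPL. Of the proliferation list, 0 of 20 rose, 18 fell and 2 did not pass (camera adjusted p = 2.3e-09). Proliferation calls were 0 and 18 adjusted over the list alone, and the list gave adjusted p = 0.078 with an estimated correlation. Col1a1 (2.47, SE 0.701), Col3a1 (2.98, SE 0.585) and Lum (4.38, SE 0.534) were higher in UPPL, while Pdgfra did not pass. Of the fibroblast list, 13 of 19 rose, 0 fell and 6 did not pass (camera adjusted p = 0.0097). Fibroblast calls were 15 and 0 adjusted over the list alone, and the list gave adjusted p = 0.66 with an estimated correlation. Vim, the mesenchymal filament gene (-3.25, SE 0.249), and Axl (-3.12, SE 0.297) were lower and Snai2 higher (2.89, SE 0.178), and the mesenchymal list did not pass (camera adjusted p = 0.67). Myh4, a fast muscle myosin gene (5.68 ± 11.4 against 2415 ± 853; -10.02, SE 1.80), Acta1 and Ckm were lower, and of the skeletal muscle list, 0 of 12 rose, 12 fell and 0 did not pass (camera adjusted p = 2.6e-04). Skeletal muscle calls were 0 and 12 adjusted over the list alone, and the list gave adjusted p = 0.49 with an estimated correlation. Acta1 stood at 3.85 and Ckm at 1.93 in the MB49 culture, and at 1.87 and 0 in the UPPL1541 culture. The cultures thus did not hold these 2 genes at the level of the MB49 tumours, and the source of the reads was not tested. Nqo1 (4.72, SE 0.645) and Gclc (1.42, SE 0.191) were higher. Of the NRF2 list, 12 of 19 rose, 4 fell and 3 did not pass (camera adjusted p = 0.044). NRF2 calls were 12 and 4 adjusted over the list alone, and the list gave adjusted p = 0.49 with an estimated correlation. Ntrk3, a neurotrophin receptor gene, and Fgf15 were listed at 0 in all UPPL tumours and stood at 1658 ± 940.2 and 1344 ± 617 in MB49. In all, 7073 of 13826 genes passed, 3834 higher and 3239 lower; the tumours of a group share a line, so these p-values measure the spread between tumours of 1 line. The median of all genes moved from 0.038 to -0.12 under quantile normalization.

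Interferon and antigen presentation genes were also lower in the 4 UPPL than in the 2 BBN line-derived tumours. Rsad2, an antiviral gene, stood at 56.9 ± 11.6 against 439 ± 56.2 (log2 fold change -2.94, SE 0.308, adjusted p = 1.1e-04), with Isg15 (-2.79, SE 0.423) lower and Cxcl9 not passed. Of the interferon list, 0 of 24 rose, 19 fell and 5 did not pass (camera adjusted p = 3.4e-16). Interferon genes called numbered 0 and 24 adjusted over the list alone, and the list gave adjusted p = 0.57 with an estimated correlation. B2m (-2.49, SE 0.704), Tap1 (-2.87, SE 0.582) and Tap2 (-2.56, SE 0.354) were lower. Of the MHC class I list, 0 of 17 rose, 13 fell and 4 did not pass (camera adjusted p = 1.9e-09). MHC class I genes called numbered 0 and 15 adjusted over the list alone, and the list gave adjusted p = 0.58 with an estimated correlation. Of the class II list, 0 of 11 rose, 5 fell and 6 did not pass (camera adjusted p = 9.3e-04). MHC class II genes called numbered 0 and 6 adjusted over the list alone, and the list gave adjusted p = 0.58 with an estimated correlation. Gzmb (-5.03, SE 1.03) and Cd8a (-5.27, SE 1.55) were lower. Of the cytotoxic list, 0 of 18 rose, 7 fell and 11 did not pass (camera adjusted p = 4.7e-06). Cytotoxic genes called numbered 0 and 10 adjusted over the list alone, and the list gave adjusted p = 0.58 with an estimated correlation. Of the T cell list, 0 of 17 rose, 3 fell and 14 did not pass (camera adjusted p = 7.0e-04). T cell genes called numbered 0 and 2 adjusted over the list alone, and the list gave adjusted p = 0.58 with an estimated correlation. Egln3, an oxygen-sensing hydroxylase gene, stood at 5643 ± 1679 against 44530.2 ± 8004 (-3.01, SE 0.290), Slc2a1, the glucose transporter gene, was lower (-1.04, SE 0.229) and Vegfa did not pass. Of the hypoxia list, 0 of 18 rose, 11 fell and 7 did not pass (camera adjusted p = 2.8e-11). Hypoxia genes called numbered 0 and 16 adjusted over the list alone, and the list gave adjusted p = 0.57 with an estimated correlation. Top2a (-0.75, SE 0.151) and Cdk1 (-1.05, SE 0.137) were lower. Of the proliferation list, 1 of 20 rose, 13 fell and 6 did not pass (camera adjusted p = 4.6e-10). Proliferation genes called numbered 1 and 16 adjusted over the list alone, and the list gave adjusted p = 0.25 with an estimated correlation. Csf1r (0.88, SE 0.256) and Fcgr3 (1.18, SE 0.207) were higher and Cd68 not passed. The Csf1r call was lost under quantile normalization (adjusted p = 0.097) and median-of-ratios scaling (0.080). Of the macrophage list, 9 of 20 rose, 0 fell and 11 did not pass (camera adjusted p = 0.027). Macrophage genes called numbered 9 and 0 adjusted over the list alone, and the list gave adjusted p = 0.58 with an estimated correlation.

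Keratins differed by gene between the UPPL and BBN line-derived tumours. Krt20 (4277 ± 1198 against 305 ± 78.1; 3.79, SE 0.618), Krt8 (2.90, SE 0.362) and Krt18 (2.01, SE 0.227) were higher in UPPL. Of the luminal list, 9 of 26 rose, 4 fell and 13 did not pass (camera adjusted p = 0.67). Luminal genes called numbered 9 and 4 adjusted over the list alone, leaning to lower values against a list median of 0.087. Krt5 and Krt14 did not pass, Egfr was higher (1.58, SE 0.236) and Itgb4, a hemidesmosome integrin gene, lower (-1.43, SE 0.298). Of the basal list, 1 of 24 rose, 4 fell and 19 did not pass (camera adjusted p = 0.0042). Basal genes called numbered 1 and 4 adjusted over the list alone, and the list gave adjusted p = 0.58 with an estimated correlation, and camera gave 0.21 under quantile normalization. Krt10 (161784 ± 51446 against 1039.7 ± 266; log2 fold change 7.25, SE 0.300, adjusted p = 2.9e-07) and Krt1 (141057 ± 43826 against 1098 ± 459; 7.02, SE 0.303; adjusted p = 0.073 in a fit over all 36 libraries), keratins of cornifying epithelium, were higher in UPPL. Of the squamous list, 6 of 19 rose, 1 fell and 12 did not pass (camera adjusted p = 0.88). Squamous genes called numbered 6 and 3 adjusted over the list alone, while fry, another list test, gave adjusted p = 0.0072 for higher values. Slc5a7, a choline transporter gene (1616 ± 943), and Trh, a hypothalamic hormone gene (1517 ± 1076), were listed at 0 in BBN tumours, and Lrmp rose by 10.04, SE 0.955 on the log2 scale. Xist, transcribed from the inactive X chromosome, was listed at 0 in UPPL tumours and stood at 5577 ± 2115 in BBN. Primary tumour UPPL1541 held Ddx3y, a Y chromosome gene, at 1029.9 and Xist at 0. Primary tumour BBN963 held Xist at 2945 and Ddx3y at 0. Sex and model therefore cannot be told apart between these lines. Chi3l4 (-8.57, SE 1.16) and the epithelial cytokine gene Tslp (-7.83, SE 1.05) were lower. The skeletal muscle list was lower by camera alone (camera adjusted p = 0.0053, adjusted p = 0.58 with an estimated correlation). Its genes stood high in only 1 of the 2 BBN tumours, with Myh4 at 1246 in tumour 2 and 0 in tumour 1. The smooth muscle list was lower by camera alone too (camera adjusted p = 0.037, adjusted p = 0.58 with an estimated correlation, and camera gave 0.086 under median-of-ratios scaling). In all, 4208 of 14604 genes passed, 3132 higher and 1076 lower, against 1887 and 1719 under quantile normalization, 2435 and 1645 under median-of-ratios scaling and 1871 and 1619 with edgeR. The median of all genes moved from 0.32 to 0.023 under quantile normalization. Other totals were 1617 in a fit over all 36 libraries, 2682 with the replicate block and 2555 without BBN tumour 1. In a simulation with these group sizes, 52 unchanged genes were called beside 72 of 200 changed ones. BBN has 2 tumours here and no score could pass (smallest exact permutation p = 0.13).

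The 2 BBN line-derived tumours shared the epithelial genes of the UPPL tumours when set against MB49. Krt6b, a keratin of activated epithelium, stood at 48119.9 ± 11026 against 0.527 ± 0.608 (log2 fold change 15.02, SE 0.365, adjusted p = 4.4e-10), Krt5 rose by 14.42, SE 0.509, Dsp by 14.59, SE 0.351 and Cdh1 by 8.50, SE 0.424 on the log2 scale; Krt13 (37376 ± 12685), Ivl, Cldn4 and Psca were listed at 0 in MB49. Of the squamous list, 19 of 19 rose, 0 fell and 0 did not pass (camera adjusted p = 1.9e-22). Squamous calls were 19 and 0 adjusted over the list alone, and the list gave adjusted p = 0.024 with an estimated correlation. Of the basal list, 20 of 24 rose, 2 fell and 2 did not pass (camera adjusted p = 3.1e-17). Basal calls were 21 and 3 adjusted over the list alone, and the list gave adjusted p = 0.037 with an estimated correlation. Of the junction list, 15 of 17 rose, 1 fell and 1 did not pass (camera adjusted p = 1.1e-13). Junction calls were 16 and 1 adjusted over the list alone, and the list gave adjusted p = 0.024 with an estimated correlation. Krt20 was higher (7.70, SE 0.618) and Krt18, a simple epithelial keratin gene, lower (-6.18, SE 0.227). Of the luminal list, 16 of 26 rose, 5 fell and 5 did not pass (camera adjusted p = 3.3e-04). Luminal calls were 16 and 6 adjusted over the list alone, and the list gave adjusted p = 0.19 with an estimated correlation. Egln3 (4.57, SE 0.290), Slc2a1 (2.03, SE 0.229) and Vegfa (1.86, SE 0.412) were higher. Of the hypoxia list, 9 of 18 rose, 0 fell and 9 did not pass (camera adjusted p = 2.9e-04). Hypoxia calls were 9 and 0 adjusted over the list alone, and the list gave adjusted p = 0.76 with an estimated correlation. Csf1r (-1.79, SE 0.256), Cd68 (-1.15, SE 0.273) and Msr1 (-4.13, SE 0.235) were lower. Of the macrophage list, 2 of 20 rose, 17 fell and 1 did not pass (camera adjusted p = 3.3e-04). Macrophage calls were 2 and 17 adjusted over the list alone, and the list gave adjusted p = 0.46 with an estimated correlation. Nqo1 rose (6.23, SE 0.794) and Gclc fell. Of the NRF2 list, 11 of 19 rose, 3 fell and 5 did not pass (camera adjusted p = 0.011). NRF2 calls were 11 and 3 adjusted over the list alone, and the list gave adjusted p = 0.46 with an estimated correlation. Fos, an early response gene, rose (2.08, SE 0.496) and Jun fell. Gclc lost its call under quantile normalization (adjusted p = 0.19), and both Gclc and Jun did under median-of-ratios scaling (0.084 to 0.085). Of the dissociation and stress list, 9 of 13 rose, 3 fell and 1 did not pass (camera adjusted p = 0.0092). Dissociation calls were 9 and 3 adjusted over the list alone, and the list gave adjusted p = 0.46 with an estimated correlation. Msln, which encodes mesothelin, Faim2 and Rgs17 were listed at 0 in BBN and stood at 4782 ± 992, 2951 ± 492 and 2310.1 ± 216 in MB49. In all, 6121 of 14604 genes passed, 2309 higher and 3812 lower (2914 and 2826 with edgeR), and the median of all genes moved from -0.24 to -0.060 under median-of-ratios scaling. In a simulation with these group sizes, 61 unchanged genes were called beside 84 of 200 changed ones.

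The UPPL minus BBN difference was not the same in line-derived as in primary tumours. Each model has 1 line here, and the fit takes tumours of 1 line as replicates. A change in the model difference therefore cannot be told apart from traits of these single lines. Hmox1 was higher in UPPL than in BBN primary tumours and lower in UPPL than in BBN line-derived tumours (1273 ± 534 against 3545 ± 1478; interaction log2 fold change -3.68, SE 0.757, adjusted p = 0.0040), and Ndrg1 (-4.77, SE 0.955) and Hk2 (-2.58, SE 0.562), which respond to low oxygen, moved the same way. Of the hypoxia list, 0 of 18 rose, 6 fell and 12 did not pass (camera adjusted p = 1.7e-16). Hypoxia genes called numbered 0 and 12 adjusted over the list alone, and the list gave adjusted p = 0.13 with an estimated correlation. Lyz2, a lysozyme gene of macrophages, (3.12, SE 0.736) and Fcgr3 (2.71, SE 0.708) moved upwards. Of the macrophage list, 3 of 20 rose, 0 fell and 17 did not pass (camera adjusted p = 8.8e-04). Macrophage genes called numbered 10 and 0 adjusted over the list alone, and the list gave adjusted p = 0.45 with an estimated correlation. The Trp53 difference was smaller in line-derived tumours as deposited (log2 fold change 1.92, SE 0.606, adjusted p = 0.046). That call was lost under quantile normalization (0.73, adjusted p = 0.48) and median-of-ratios scaling (1.5998, adjusted p = 0.091). Expi, a protease inhibitor gene, Lrmp (12.23, SE 2.34) and the cartilage collagen gene Col10a1 moved most upwards, with Expi and Col10a1 listed at 0 in the 2 BBN line-derived tumours, and Tslp (-9.02, SE 2.72), Cyp2b10 (-7.98, SE 1.92) and the mucin enzyme gene Gcnt3 (-6.91, SE 1.58) most downwards. In all, 1404 of 15229 genes passed, 1243 upwards and 161 downwards, against 447 and 328 under quantile normalization, 693 and 323 under median-of-ratios scaling and 194 and 218 with edgeR. The median of all genes moved from 0.55 to 0.070 under quantile normalization. The total was 296 without BBN line-derived tumour 1 and 299 without the 5 libraries short of low reads, in which the most frequent low value was 10 reads or more. In the simulation 22 unchanged genes were called beside 34 of 200 changed ones. Across 12720 genes the UPPL minus BBN log2 fold changes of primary and line-derived tumours had a Pearson correlation of 0.124, and 57.3 percent of 2344 genes called in primary tumours had the same sign in line-derived tumours (44.2 by chance from the shares of each sign). Under quantile normalization the correlation was 0.163 and the share 64.2 percent (49.99 by chance). Without the primary tumours whose numbers the lines carry, they were 0.0825 and 54.4 percent (44.1 by chance). Genes called in each and higher in UPPL numbered 229 (152 by chance), lower 268 (129 by chance), and opposite 279 (408 by chance), or 142 opposite under quantile normalization (241 by chance).

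Luminal genes fell and stromal genes rose from UPPL primary tumours to tumours of the UPPL1541 line. The 4 line-derived tumours share 1 line, so these changes cannot be told apart from traits of that line. The luminal score was 11.59 in primary tumour UPPL1541 and 8.08 in the single library of the UPPL1541 culture. It was 7.98 ± 0.208 in the line's tumours, so the culture already stood near its tumours. Upk1b fell from 15139 ± 13057 to 8.87 ± 5.35 (log2 fold change -10.05, SE 1.498, adjusted p = 2.5e-05), Upk2 fell from 1771 ± 1673 to 8.05 ± 3.32, Pparg from 2191 ± 709 to 31.6 ± 11.2 and Tmprss2 from 8101 ± 5850.0 to 142 ± 77.4, while Krt20 rose (2.72, SE 0.975; adjusted p = 0.059 under median-of-ratios scaling); Upk3b and Vsig2 (2618 ± 631 in primary tumours) ended listed at 0. Of the luminal list, 1 of 29 rose, 18 fell and 10 did not pass (camera adjusted p = 4.4e-14). Luminal calls were 3 and 18 adjusted over the list alone, and the list gave adjusted p = 0.040 with an estimated correlation. Of the squamous list, 9 of 19 rose, 1 fell and 9 did not pass, with a list median of 5.06. The squamous list did not pass as a whole (camera adjusted p = 0.079, adjusted p = 0.69 with an estimated correlation). Gstm1 (-4.97, SE 0.805), Nqo1 (-3.68, SE 0.790) and Gclc (-1.42, SE 0.345) fell. Of the NRF2 list, 0 of 20 rose, 12 fell and 8 did not pass (camera adjusted p = 2.4e-10). NRF2 calls were 0 and 14 adjusted over the list alone, and the list gave adjusted p = 0.042 with an estimated correlation. Cdh1 (-1.01, SE 0.259) and Cldn4 (-2.04, SE 0.423) fell. Of the junction list, 0 of 17 rose, 8 fell and 9 did not pass (camera adjusted p = 8.2e-07). Junction calls were 0 and 8 adjusted over the list alone, and the list gave adjusted p = 0.068 with an estimated correlation. Acsl3 fell (-1.63, SE 0.268) and Angptl4 did not pass. Of the PPAR list, 3 of 16 rose, 5 fell and 8 did not pass (camera adjusted p = 0.026). PPAR calls were 3 and 5 adjusted over the list alone, and the list gave adjusted p = 0.34 with an estimated correlation, and camera gave 0.14 under quantile normalization. Vegfa fell (-1.29, SE 0.483; hypoxia list camera adjusted p = 0.048, adjusted p = 0.67 with an estimated correlation, and camera gave 0.43 under quantile normalization), Hspa1a, a heat shock gene, fell (-2.77, SE 0.481) and Fos and Jun did not pass (dissociation list camera adjusted p = 0.0034, adjusted p = 0.31 with an estimated correlation).

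Macrophage and fibroblast genes rose from UPPL primary to UPPL line-derived tumours, which are 4 tumours of 1 line. Csf1r rose from 85.7 ± 84.7 to 1231 ± 438 (log2 fold change 4.24, SE 0.625, adjusted p = 2.1e-05), Lyz2 by 3.88, SE 0.454 and Cd68 by 1.22, SE 0.422. The Cd68 call was lost under quantile normalization (adjusted p = 0.13) and median-of-ratios scaling (0.071). In the single library of the UPPL1541 culture, Csf1r stood at 360 and Cd68 at 124. Reads of these 2 genes in the tumours therefore need not come from macrophages alone. Of the macrophage list, 19 of 20 rose, 0 fell and 1 did not pass (camera adjusted p = 9.5e-11). Macrophage calls were 19 and 0 adjusted over the list alone, and the list gave adjusted p = 0.081 with an estimated correlation. Col1a1 rose from 417 ± 254 to 46516 ± 26022 and Postn, a matrix protein gene, by 6.99, SE 0.890; of the fibroblast list, 17 of 19 rose, 0 fell and 2 did not pass (camera adjusted p = 2.5e-11). Fibroblast calls were 18 and 0 adjusted over the list alone, and the list gave adjusted p = 0.23 with an estimated correlation. Vim (3.70, SE 0.573) and Zeb1 (4.00, SE 1.001) rose. Of the mesenchymal list, 14 of 17 rose, 0 fell and 3 did not pass (camera adjusted p = 6.3e-06). Mesenchymal calls were 14 and 0 adjusted over the list alone, and the list gave adjusted p = 0.14 with an estimated correlation. Cd74 (3.20, SE 0.557) and H2-Aa (3.42, SE 0.558) rose. Among MHC class II genes, 9 of 10 rose, 0 fell and 1 did not pass (camera adjusted p = 1.9e-05). MHC class II calls were 9 and 0 adjusted over the list alone, and the list gave adjusted p = 0.24 with an estimated correlation. S100a8, a neutrophil alarmin gene (5.86, SE 1.17), and Csf3r (6.15, SE 1.16) rose. Of the neutrophil list, 9 of 14 rose, 0 fell and 5 did not pass (camera adjusted p = 5.5e-04). Neutrophil calls were 11 and 0 adjusted over the list alone, and the list gave adjusted p = 0.24 with an estimated correlation. Cd274 rose (1.88, SE 0.473; checkpoint list camera adjusted p = 0.0073, adjusted p = 0.24 with an estimated correlation), as did Cxcl9 (6.77, SE 1.26; interferon list camera adjusted p = 0.045, adjusted p = 0.69 with an estimated correlation). C1qtnf3 (11.76, SE 1.31), the squamous protease inhibitor gene Serpinb3a (11.24, SE 1.87) and the matrix gene Tnn (10.73, SE 0.841) rose most. In all, 3960 of 14483 genes passed, 3048 rose and 912 fell, against 1784 and 1765 under quantile normalization, 2320 and 1310 under median-of-ratios scaling and 1602 and 1539 with edgeR, and the median of all genes moved from 0.36 to -0.027 under quantile normalization.

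Lymphocyte and hypoxia genes rose from the 11 BBN primary tumours to the 2 tumours of the BBN963 line. These 2 tumours share 1 line, so the changes cannot be told apart from traits of that line. Gzmb rose from 9.14 ± 9.43 to 324 ± 148 (log2 fold change 5.85, SE 1.44, adjusted p = 0.012) and Ifng, the interferon gamma gene, by 4.71, SE 0.733, and Cd8a did not pass. Of the cytotoxic list, 9 of 16 rose, 0 fell and 7 did not pass (camera adjusted p = 5.6e-13). Cytotoxic genes called numbered 13 and 0 adjusted over the list alone, and the list gave adjusted p = 0.023 with an estimated correlation. Cd3e (4.23, SE 1.26) and Lat (4.94, SE 0.875) rose. Of the T cell list, 8 of 17 rose, 0 fell and 9 did not pass (camera adjusted p = 1.7e-08). T cell genes called numbered 11 and 0 adjusted over the list alone, and the list gave adjusted p = 0.091 with an estimated correlation. Egln3 (5.03, SE 0.874) and Pgk1 (2.08, SE 0.435) rose, while Vegfa and Slc2a1 did not pass. Of the hypoxia list, 9 of 18 rose, 0 fell and 9 did not pass (camera adjusted p = 5.5e-13). Hypoxia genes called numbered 15 and 0 adjusted over the list alone, and the list gave adjusted p = 0.096 with an estimated correlation. B2m (2.74, SE 0.828) and Cd74 (3.30, SE 0.711) rose. Of the MHC class I list, 6 of 17 rose, 0 fell and 11 did not pass (camera adjusted p = 6.2e-10). MHC class I genes called numbered 12 and 0 adjusted over the list alone, and the list gave adjusted p = 0.11 with an estimated correlation. Of the class II list, 6 of 11 rose, 0 fell and 5 did not pass (camera adjusted p = 9.0e-08). MHC class II genes called numbered 9 and 0 adjusted over the list alone, and the list gave adjusted p = 0.12 with an estimated correlation. Cxcl9 rose (6.10, SE 1.62). Of the interferon list, 7 of 24 rose, 0 fell and 17 did not pass (camera adjusted p = 9.1e-11). Interferon genes called numbered 11 and 0 adjusted over the list alone, and the list gave adjusted p = 0.15 with an estimated correlation. Krt18 fell (-4.06, SE 0.915) and Krt20 did not pass. Of the luminal list, 0 of 30 rose, 8 fell and 22 did not pass (camera adjusted p = 0.012). Luminal genes called numbered 1 and 11 adjusted over the list alone, and the list gave adjusted p = 0.40 with an estimated correlation. Tnn (9.93, SE 1.08), Crabp1, a retinoic acid binding protein gene (7.88, SE 0.916), and Lrrc15 (7.84, SE 1.77) rose most, and Upk1b, Upk2, Fxyd4 and Itga2 ended listed at 0. Macrophage genes passed as a list and no member passed alone (camera adjusted p = 2.7e-04, adjusted p = 0.29 with an estimated correlation). Lists of other cell types passed upwards as well: fibroblast and matrix genes (1 of 19 rose, median 3.11, camera adjusted p = 4.2e-07), skeletal muscle (4 of 11, median 4.03, camera adjusted p = 3.7e-06) and mast cells and eosinophils (4 of 8, median 4.69, camera adjusted p = 2.7e-05). The muscle genes stood far higher in 1 of the 2 tumours, with Myl1 at 523 in tumour 2 and 2.54 in tumour 1. Also passing upwards were the proliferation, checkpoint, squamous, neutrophil, B cell and mesenchymal lists (camera adjusted p 2.1e-08 to 0.045), and junction genes passed downwards (0.045). None of these held with an estimated correlation (adjusted p 0.096 to 0.53). In all, 1182 of 15229 genes passed, 318 rose and 864 fell, against 427 and 678 under median-of-ratios scaling and 313 and 416 with edgeR, and the median of all genes moved from -0.17 to -0.032. The total was 232 without BBN tumour 1 and 309 without the libraries short of low reads. In a simulation with these group sizes, 114 unchanged genes were called beside 71 of 200 changed ones.

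Collagen, complement and MHC class II genes marked the 10 line-derived tumours against the 3 cultures of their lines. Col3a1 stood at 110803 ± 53034, 26489 ± 2417 and 16745 ± 16573 in UPPL, BBN and MB49 tumours and at 1.87, 0 and 0 in the 3 cultures (log2 fold change 14.43, SE 0.533, adjusted p = 6.6e-10); Col1a2 rose by 13.29, SE 0.709 and Col1a1 by 10.18, SE 0.744 on the log2 scale. Of the fibroblast list, 19 of 19 rose, 0 fell and 0 did not pass (camera adjusted p = 3.1e-17). Fibroblast calls were 19 and 0 adjusted over the list alone, and the list gave adjusted p = 0.090 with an estimated correlation. C1qa and C1qb were listed at 0 in all cultures; of the macrophage list, which holds Csf1r (7.28, SE 1.18) and Cd68 (1.99, SE 0.289), 20 of 20 rose, 0 fell and 0 did not pass (camera adjusted p = 3.7e-19). Macrophage calls were 20 and 0 adjusted over the list alone, and the list gave adjusted p = 0.090 with an estimated correlation. Csf1r stood at 360 in the UPPL1541 culture and was listed at 0 in the BBN963 and MB49 cultures. Cd68 stood at 124, 247 and 172 in the UPPL1541, BBN963 and MB49 cultures, so cultured cells hold it too. H2-Aa (12.83, SE 0.358) and Cd74 (8.32, SE 0.907) rose. Among MHC class II genes, 11 of 11 rose, 0 fell and 0 did not pass (camera adjusted p = 2.2e-10). MHC class II calls were 11 and 0 adjusted over the list alone, and the list gave adjusted p = 0.090 with an estimated correlation. Pecam1 (5.61, SE 0.458) and Cdh5 (7.86, SE 0.607) rose. Of the endothelial list, 12 of 14 rose, 0 fell and 2 did not pass (camera adjusted p = 6.4e-09). Endothelial calls were 13 and 0 adjusted over the list alone, and the list gave adjusted p = 0.090 with an estimated correlation. Sprr1b (5.20, SE 0.530) and Ivl (1.39, SE 0.470) rose. Of the squamous list, 19 of 19 rose, 0 fell and 0 did not pass (camera adjusted p = 6.6e-08). These changes are averages over the 3 lines. Ivl was listed at 0 in the MB49 culture and in every MB49 tumour. Squamous calls were 19 and 0 adjusted over the list alone, and the list gave adjusted p = 0.22 with an estimated correlation. Bnip3, a hypoxia-induced mitochondrial gene (3.13, SE 0.295), and Slc2a1 (0.91, SE 0.215) rose, and Vegfa did not pass. Of the hypoxia list, 12 of 18 rose, 0 fell and 6 did not pass (camera adjusted p = 6.1e-05). Hypoxia calls were 12 and 0 adjusted over the list alone, and the list gave adjusted p = 0.22 with an estimated correlation. Cxcl9 rose (10.33, SE 1.13). Of the interferon list, 21 of 24 rose, 0 fell and 3 did not pass (camera adjusted p = 8.6e-08). Interferon calls were 22 and 0 adjusted over the list alone, and the list gave adjusted p = 0.29 with an estimated correlation. The lists of mesenchymal, smooth and skeletal muscle, regulatory T, B, dendritic and mast cell, checkpoint, MHC class I, PPAR, haemoglobin and dissociation genes passed upwards too (camera adjusted p 1.0e-04 to 0.024), and none held with an estimated correlation.

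Other immune lists also rose from culture to tumour, among them T cell genes such as Cd3e (listed at 0 in all 3 cultures; list camera adjusted p = 9.7e-06, adjusted p = 0.22 with an estimated correlation), cytotoxic genes such as Gzmb (also listed at 0 there; list camera adjusted p = 1.4e-04, adjusted p = 0.29 with an estimated correlation) and neutrophil genes such as S100a8 (9.25, SE 0.607; list camera adjusted p = 4.4e-06, adjusted p = 0.22 with an estimated correlation). Mcm2 (-0.75, SE 0.132) and Rrm2 (-0.94, SE 0.282), which serve DNA replication, fell, while Mki67 and Top2a did not pass. Of the proliferation list, 0 of 20 rose, 2 fell and 18 did not pass (camera adjusted p = 0.0012). Proliferation calls were 0 and 1 adjusted over the list alone, and the list gave adjusted p = 0.46 with an estimated correlation. Paqr3 (-4.79, SE 1.13), the chemokine gene Ccl20 (-4.74, SE 0.846) and Tmem56 (-4.73, SE 1.15) fell most. In all, 4163 of 14321 genes passed, 2876 rose and 1287 fell, against 2152 and 2203 under quantile normalization and 2396 and 1777 with edgeR, and the median of all genes moved from 0.13 to -0.13 under quantile normalization. The culture side holds 1 library per line, so the spread comes from the tumours and from how far the step from culture to tumour differs between lines.

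In culture, the UPPL1541 line kept low Trp53 (50.4, against 3017 in BBN963, 1937 in MB49 and 1219 ± 139.5 in 3 KT lines, mean ± SD). Krt5 was abundant in UPPL1541 (67387), BBN963 (106940.0) and KT (54622 ± 7155) and stood at 0.964 in MB49. Cdh1 ran alike (33287, 9955, 16548 ± 13016 and 0.964), and Vim stood at 19076 in MB49 against 139 in UPPL1541, 417 in BBN963 and 6772 ± 2835 in KT. Mki67 was 15649 in UPPL1541, 12149.6 in BBN963, 3035 in MB49 and 2095 ± 857 in KT. Mdm2, a p53 target, stood at 961.7 in UPPL1541, 2293 in BBN963, 15328 in MB49 and 22706 ± 16987 in KT. The KT lines were unlike in Mdm2 (4589 in KT1044, 25253 in KT1970 and 38275 in KT1975). Cells of each line were sequenced once, so the lines are described without a test.

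**Figure D5:**
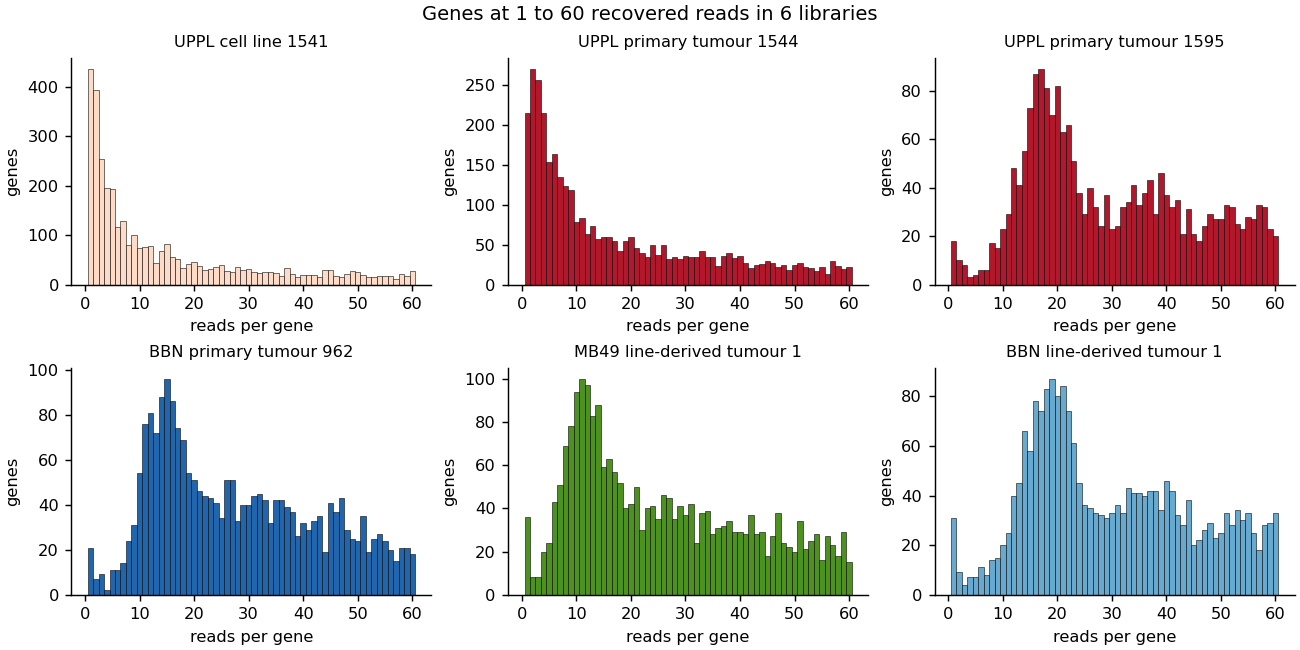
Number of genes at each count from 1 to 60 recovered reads in 6 libraries. Genes of the UPPL culture pile up at 1 read, while those of primary tumour UPPL1595 peak at 16 and those of BBN line-derived tumour 1 at 19 reads.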

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

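The tests of the 3 patterns weighed here were chosen, and the counts over other splits of the samples written down, only after the results were seen.

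Primary tumour UPPL1694 lay far from the other 8 in its basal score (9.30, others 12.34 to 13.22) and in luminal minus basal (2.13, others -3.28 to -0.70). UPPL line-derived tumour 1 lay apart in luminal minus basal (-5.18, others -4.65 to -4.55), and tumour 2 in the fibroblast score (10.89, others 12.65 to 12.99). These are 4 of 32 groups and scores checked, and chance flags about 1 in 20 groups. The 2 flags of UPPL1694 share its basal score. Only UPPL primary, UPPL line-derived and MB49 line-derived tumours entered this check, so BBN tumours did not. Among BBN primary tumours, BBN974 had the highest cytotoxic score (3.16), with BBN975 next (1.72).

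The UPPL minus BBN difference differed between line-derived and primary tumours, by a test of that difference, in 1404 genes, a count that fell to 296 without BBN line-derived tumour 1 and to 412 with edgeR. Among named genes the differences were 1.92 for Trp53, 12.49 for Expi, 12.23 for Lrmp, 11.99 for Col10a1, -9.02 for Tslp, -7.98 for Cyp2b10 and -6.91 for Gcnt3 on the log2 scale; Expi and Col10a1 were listed at 0 in the BBN line-derived tumours, so their sizes rest on the added 1. The Trp53 value was 0.73 and not passed under quantile normalization (adjusted p = 0.48), so it depends on the scaling. List medians of the difference were -1.16 for luminal, -0.106 for basal, -0.37 for junction, 3.36 for mesenchymal, 3.48 for fibroblast, -2.81 for skeletal muscle, -0.65 for T cell, -2.09 for cytotoxic, 2.55 for macrophage, -1.83 for mast cell, -0.66 for MHC class I, -0.60 for interferon, -0.46 for proliferation, -0.85 for NRF2, -1.60 for hypoxia and -0.37 for dissociation genes. None of these list calls held with an estimated correlation. Camera sets a list against the other genes, and the median of all genes was 0.55 as deposited and 0.070 under quantile normalization. The basal, junction, skeletal muscle, mast cell and proliferation lists had 0 genes called. Each model has 1 line, so these differences cannot be told apart from traits of single lines.

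Other splits of the same samples called fewer genes than the real split in 4 comparisons. The counts were 2371 for primary tumours against at most 1, and 7073 for UPPL and MB49 tumours against at most 15. They were 3960 for UPPL line-derived and primary tumours against at most 684, and 4163 for tumours and cultures against at most 268. The real split came first (1 of 100, 1 of 35, 1 of 100 and 1 of 75 splits), so a random split is an unlikely source of these counts. Line-derived tumours of a group share 1 line, so the splits cannot tell a difference between models from one between single lines.

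Few genes of some tumour libraries had 1 to 5 reads. Among genes at about 5 expected reads, 58.7 to 80.6 percent were listed at 0 in 4 libraries, within 7.77 points of the share expected of PCR copies of few molecules. Copying also needs their mean reads to stay near the expected, and these were 1.09 to 2.15 times that. Libraries whose most frequent low value was below 5 reads gave 0.757 to 4.68 times and 19.2 to 58.0 percent at 0, so the expected reads are too uncertain to decide for copies or against a cutoff that set low values to 0, and both stay open. No biological explanation was tested.

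Immune lists were lower in UPPL than in BBN primary tumours. Their 4 scores per tumour differed by -0.99 to -2.33 as deposited and by -0.86 to -2.22 under median-of-ratios scaling (exact permutation adjusted p at most 0.0095), which argues against scaling as the sole cause. Leaving out the libraries short of low reads left the largest camera adjusted p at 0.0070, which argues against those libraries as the sole cause. A lower share of all cells other than epithelial cells stays open: between the models the macrophage score differed by -1.504, the endothelial by -0.63, the fibroblast by -1.99 and the smooth muscle score by -2.22. Macrophage minus each of the others did not pass (exact permutation adjusted p 0.12 to 0.49). The biological explanation, fewer or less active immune cells in UPPL tumours, stays a hypothesis, since it was found and tested on the same tumours, and no list held with an estimated correlation.

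Trp53 reads remained in UPPL tumours. If stromal and immune cells were their sole source, Trp53 would rise with those cells in line-derived tumours. Its change was 0.45 (SE 0.373, upper 95 percent limit 1.21) against a median rise of at least 3.69 in the macrophage and fibroblast lists. That argues against these cells as the sole source. Trp53 also stood at 50.4 (54 reads) in the single library of the UPPL1541 culture. A part supplied by stromal and immune cells, beside reads from tumour cells, stays open. Transcript left from the recombined gene, or cells in which it did not recombine, was not tested and stays open.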

How the results depend on the processing

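Tests with edgeR, with median-of-ratios scaling of scores, and without the 5 libraries short of low reads (most frequent low value of 10 reads or more) were chosen only after the results were seen. Counts differed most in comparisons with the 2 BBN line-derived tumours. A fit over all 36 libraries gave 4698 genes for UPPL minus MB49, 1617 for UPPL minus BBN and 3772 for BBN minus MB49 line-derived tumours. The model contrast difference gave 775 genes under quantile normalization, 2740 with array weights, 412 with edgeR and 299 without the libraries short of low reads. The BBN line-derived minus primary comparison gave 1810 with array weights, 729 with edgeR and 309 without those libraries. Array weights gave 6579 for UPPL line-derived minus primary tumours and 2134 for tumours minus cultures. The replicate block gave 2682 for UPPL minus BBN and changed no other count by over 1.5 times. Same-number correlations ran from -0.109 to 0.0750 and those of other pairs from -0.0813 to 0.109. They gave no sign that tumour numbers pair the samples, but cannot exclude it. The cause was not tested for any of these.

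Leaving out 1 library at a time kept every count within 1.5 times except in 3 comparisons. UPPL minus BBN line-derived tumours ranged from 2555 to 4291 (lowest without BBN tumour 1), the model contrast difference from 296 to 1680 (lowest without BBN tumour 1), and BBN line-derived minus primary from 232 to 1520 (lowest without BBN tumour 1). The difference also gave 920.0 without BBN tumour 2 and 841 without UPPL tumour 1, and BBN line-derived minus primary gave 653 without BBN tumour 2. With 1 BBN tumour left, that tumour is assumed to vary like the other groups.

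Among primary scores, the junction difference passed under median-of-ratios scaling (0.48, exact permutation adjusted p = 0.017) and ranged from 0.25 to 0.41 with 1 tumour left out. The T cell difference no longer passed under quantile normalization (-0.46) or without the libraries short of low reads (-0.82). The fibroblast difference no longer passed under quantile normalization (-1.79), median-of-ratios scaling (-1.87) or without those libraries (-1.79), and ranged from -2.38 to -1.69 with 1 tumour left out. In the exact permutation test the Upk3a difference passed without those libraries (5.11, adjusted p = 0.037), while by limma it passed under no alternative. The cause was not tested.

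The 6 passing scores of UPPL minus MB49 tumours no longer passed with any 1 tumour left out, because 3 against 4 tumours cannot give an exact p below the threshold: without MB49 tumour 1, the one short of low reads, they were 2.25 for luminal, 7.75 for basal, -5.50 for luminal minus basal, 6.77 for junction, -4.00 for cytotoxic, -0.84 for macrophage, and their ranges were 2.20 to 2.35 for luminal, 7.58 to 7.97 for basal, -5.71 to -5.27 for luminal minus basal, 6.77 to 7.08 for junction, -4.42 to -3.43 for cytotoxic, -0.97 to -0.72 for macrophage. The T cell difference passed under quantile normalization (-3.09).

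The most frequent low value reached 19 reads in a tumour and was 1 in every culture, so low genes and genes listed at 0 in tumours are uncertain. Read totals did not differ in that way: BBN line-derived tumours held 10.6 to 11.8 M reads and the BBN963 culture 11.3 M.

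The luminal list of UPPL minus BBN line-derived tumours was not passed by camera, which leaned to lower values. Another list test, fry, called it higher (adjusted p = 0.0483). Camera sets a list against the other genes and fry sets it against no change, so they answer different questions. The list median was 0.087 and the median of all genes 0.32.

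Across all alternatives and all libraries left out, values of named genes kept their side of the threshold 5692 times, lost a call 385 times, gained one 20 times and never reversed. Lists kept their side 534 times and lost a call 134 times, of which 95 were lost with an estimated correlation.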

Other observations

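Sex-linked genes are given as values and were not used to group. Ddx3y, a Y chromosome gene, stood at 1029.9 in primary tumour UPPL1541 and at 0.934 in the UPPL1541 culture, while the 4 tumours of that line held 136, 74.3, 194 and 70.3. Xist was listed at 0 in all 6 of these libraries. In BBN963, Xist stood at 2945 in the primary tumour, 15289.5 in culture, and 4081 and 7072 in the line's tumours, with Ddx3y listed at 0 in all 4. MB49 held Ddx3y at 2175 in culture. Comparisons of BBN963 tumours with those of UPPL1541 or MB49 thus also set libraries with Xist against libraries without it. Xist stood above 1000 with Ddx3y at or near 0 in primary tumours UPPL1591, UPPL1595, UPPL1612, BBN962, BBN963, BBN964, BBN965 and BBN968, and line KT1970.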
